A study of Homo sapiens with 54 samples.

How the data were processed

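Gene expression was measured by RNA sequencing in 54 libraries from 6 high-grade serous ovarian cancer cell lines, which form 3 sensitive and resistant pairs from the same patients. Per the labels' protocols, cells grew in RPMI medium with serum, were cultured for 48 h before treatment and received carboplatin, and 200 ng of total RNA went into a stranded total RNA kit with reads of 75 bases in pairs. The treatment protocol gives a dose of 80 µM, whereas the series text gives the same figure in mM, and µM was used here. The labels give the untreated samples a time of 0, whereas the series text describes a vehicle control harvested at 24 h. They are called untreated here. Replicate cultures were prepared on 3 different days per the series text. Per the labels, 8 h and 24 h cultures of a line with the same replicate number had the same passage in 18 of 18 cases, so these numbers pair them. As a check, the deviations of paired libraries from their group means correlated at -0.352 to 0.455.

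The deposited values were TPM, a length-adjusted share of all transcripts summed per gene, which the authors gave in 1 table of 25435 genes. The name of that table points to RSEM as the quantifier. Per the submitters' processing notes, reads were converted with bcl2fastq 2.18 and the genome build was hg19. The aligner, the annotation and the strand setting of the counting are not given in the sources used here, so antisense genes and genes with near-identical copies are reported as uncertain. Each library summed to the same total, and TPM keeps no read depth, so no counting error could be given. Exact zeros were common, also for genes that every cell uses, and may be failed estimates, so a gene at 0 is said to be listed at 0. The symbols of 28 genes had been turned into dates and were not named. Columns were tied to samples by line, time and replicate in their names, no 2 columns were identical, and a reference annotation of build GRCh38 served only for gene names, classes and transcript lengths.

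TPM values were rescaled by the median ratio over the 392 genes above 0 in all libraries and transformed as log2(value + 1). Genes with TPM of at least 1 in at least 3 libraries were tested, 18262 in all. limma 3.58.1 in R 4.3.3 was fitted once to the 18 groups of 3 libraries with a mean-variance trend, and 27 comparisons were drawn from it. They were each resistant line against its partner without drug, 8 h and 24 h against untreated and 24 h against 8 h in each line, and the difference of the treatment changes between the lines of a pair. P-values were adjusted by the Benjamini-Hochberg method within a comparison and calls were made at an adjusted p under 0.05. Genes called in all pairs or all lines were counted against the number that independent lists of the same sizes would share. The design, the named-gene rule, the gene lists and the other settings were fixed before the data were examined, except where a choice is said to have been made after seeing the data.

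Of 34 gene lists, 33 had tested members, since the mitochondrially encoded genes were not among the genes of the table. The others included fatty acid oxidation and synthesis, oxidative phosphorylation, glycolysis, cholesterol synthesis, homologous recombination, the Fanconi anaemia pathway, nucleotide excision and mismatch repair, platinum and drug transport, metallothioneins, NRF2 targets, glutathione transferases, histones, G1/S and G2/M genes, interferon-stimulated, NF-kB, immediate early, integrated stress, unfolded protein and heat shock genes, the BCL2 family, epithelial, mesenchymal, Müllerian, hypoxia and ribosomal protein genes, small structural RNAs, and markers of fibroblasts, leukocytes and endothelium. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 33 lists of a comparison. Of 900 list members 23 were absent from the table.

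Named genes followed a rule. It took genes of the study's subject, among them CPT1A, BRCA1, BRCA2, CDKN1A, MDM2, SLC31A1, ATP7A, ATP7B, ABCB1, CCNE1 and ERCC1, the 12 genes with the largest mean change among those called in all pairs or all lines, the 4 largest per direction in each pair and in each response difference, the 3 largest per direction in each line at 24 h, and up to 4 called members of each list discussed. Genes of levels under 5 rescaled TPM in the higher group, RNAs shorter than 200 bases and Y-linked genes and XIST were left out of the rule's rankings.

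After the values were seen, 12 libraries that listed fewer than 12000 genes above 0 were set aside in a model of the remaining 42, with 18013 genes tested and scaling over 8287 genes, and resistant and sensitive lines were compared within 8 h and 24 h of treatment. A block for the replicate number over the 8 h and 24 h libraries of each line was likewise added after the values were seen. The other settings fixed in advance were a pseudocount of 0.1, no filter on low values, TPM as deposited, the replicate number as a block, a fit on the compared groups only, an estimated correlation for the lists, genes called in at least 5 of 6 lines, leaving out 1 pair of lines, and leaving out each library. For each comparison all 10 splits of its 6 libraries, or 100 drawn splits for combined results, were fitted again. The code was tested on simulated data in which 200 of 18262 genes were changed. Each gene had its real spread, taken as normal, independent of other genes and the same in every library. Libraries of unequal quality and shifts of whole libraries were not simulated, so the shares and false calls below hold for that setting only. For PEO4 against PEO1 without drug it called 0% of the genes changed by a log2 of 1, 6.06% of those changed by 2 and 47% of those changed by 4, with 2 false calls. For the 24 h treatment of PEO1 the shares were 0%, 4.55% and 51.5%, for 24 h against 8 h in PEO1 they were 0%, 3.03% and 56.1%, and for the response difference of PEO4 and PEO1 at 24 h they were 0%, 3.03% and 19.7%.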

Results

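RNA was sequenced from 6 high-grade serous ovarian cancer cell lines that form 3 pairs, each pair from 1 patient and made up of a platinum-sensitive and a platinum-resistant line. The pairs were PEA1 with PEA2, PEO1 with PEO4, and PEO14 with PEO23, the sensitive line named first. Each line was measured untreated and after 8 h and 24 h in 80 µM carboplatin, a platinum drug that forms adducts and crosslinks in DNA. There were 3 replicates per group, prepared on 3 different days per the series text, which gave 54 libraries in 18 groups. The values were gene-level TPM for 25435 genes. TPM keeps no depth, so the depth of each library is unknown, and the labels give only an intended depth of more than 50 M read pairs of 75 bases. Log2 changes are on the log2(rescaled TPM + 1) scale, which understates the change of weakly expressed genes, and are given with the standard error (SE) from 1 limma model of all 18 groups. Adjusted p-values are Benjamini-Hochberg values over the 18262 genes tested, and n is 3 libraries per group unless another number is given.

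The libraries differed widely in the number of genes listed above 0 TPM, from 2678 to 17133 with a median of 14483.5. In 12 libraries fewer than 12000 genes were listed. They included the 3 untreated PEO23 libraries, with 11151, 2678 and 2985 genes, and 2 of the 3 untreated PEA1 libraries, with 11754 and 8635. The remaining 42 libraries, which listed 12877 to 17133 genes, are called the kept libraries, and each count is also given for a model of these alone. That model was chosen after seeing the data. It has 1 library each for untreated PEA1, PEO4 at 24 h and PEO14 at 24 h, which is assumed to vary like the other groups, and none for untreated PEO23. It has 2 libraries each for PEA2, PEO1 and PEO4 at 8 h, and 3 for each other group. Across 1000 genes, 51 of the 54 libraries resembled their own line most. The 3 exceptions were all untreated libraries from the set of 12. The library labelled PEA1 untreated replicate 3 correlated at 0.717 with PEA2 and at 0.344 with PEA1, PEO23 untreated replicate 3 at 0.409 with PEA1 and at 0.055 with PEO23, and PEO23 untreated replicate 2 at 0.176 with PEO14 and at 0.161 with PEO23 (correlations across genes, which are not independent replicates). Treated and untreated libraries also differed in composition. Among kept libraries the cytosolic ribosomal protein mRNAs took a median of 11.7% of TPM in untreated and 18.8% in treated libraries, and a median of 28 against 10 olfactory receptor genes, which are silent in most tissues, were listed above 0. The noncoding RNAs RMRP and RPPH1 together took 1.38% to 45.6% of TPM in a library. Of 18 pairs of untreated and treated cultures with the same line and replicate number, 1 overlapped in passage, so passage and treatment were not separated.

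**Figure D1:**
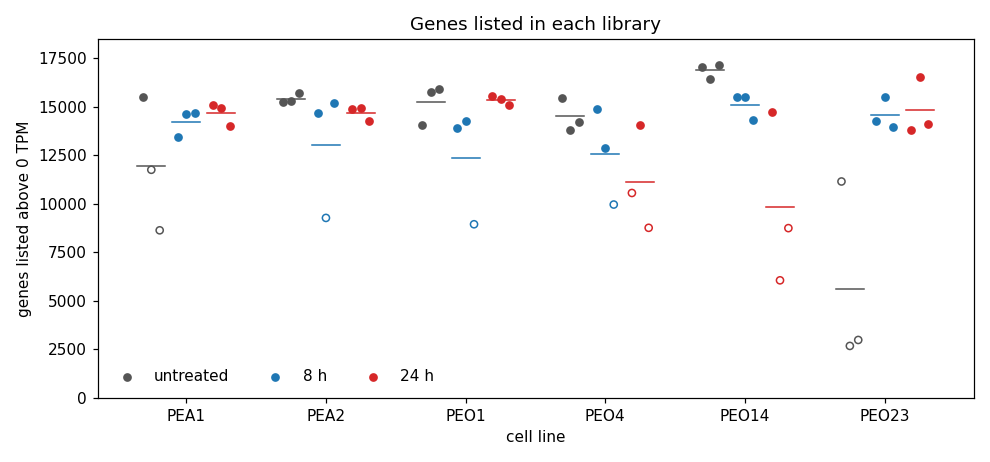
Number of genes listed above 0 TPM (y axis) in each of the 54 libraries by cell line (x axis), with untreated libraries in grey, 8 h in blue and 24 h in red. Filled points are the 42 kept libraries, open points the 12 libraries with fewer than 12000 genes, and short lines the means of 3 libraries; untreated PEO23 libraries lie at 11151, 2678 and 2985 genes.

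The first question was how each resistant line differed from its sensitive partner without drug. In the PEA pair, PEA2 expressed more of several epithelial genes. Per the labels, every PEA1 culture had a far higher passage number than any PEA2 culture. Time in culture therefore cannot be told apart from resistance in any comparison of PEA2 with PEA1, here or below. The cytokeratin KRT7 was higher by 4.47 ± 1.16 (log2 ± SE, adjusted p = 0.0166), with 781, 749 and 968 rescaled TPM in PEA2 against 6.67, 6.39 and 929 in PEA1, where the highest value came from the library labelled PEA1 untreated replicate 3. The chemokine CCL2 stood at 160, 143 and 113 in PEA2 and at 0, 0 and 9.82 in PEA1 (adjusted p = 0.000223). HAVCR1, also called KIM-1, was listed at 0 in all 3 PEA2 libraries and at 302, 236 and 65.2 in PEA1 (adjusted p = 4.75e-08). Of 22 tested epithelial markers 5 were higher and 17 did not pass, and 13 were higher when adjusted over the list alone. Their median difference was 2.13 against 0.26 for all genes, with camera's adjusted p = 1.52e-06 at a preset correlation and adjusted p = 0.682 with an estimated correlation. Of 29 NF-kB and cytokine genes, 5 were higher, among them TNF and CXCL5 (9 adjusted over the list alone; adjusted p = 0.0178, and adjusted p = 0.682 with an estimated correlation). The kept libraries hold 1 untreated PEA1 library, so the spread of that group is taken from the other groups. In them epithelial markers were again higher as a list in PEA2. The adhesion molecule EPCAM, chosen after its values were seen, was higher there by 3.38. VIM, the mesenchymal intermediate filament vimentin, differed by -4.15 in the same libraries. The glycolytic genes PFKFB3 and PFKP were lower in PEA2, and with kept libraries the glycolysis list was lower too. In all, limma called 536 genes higher and 165 lower in PEA2, and 1136 higher and 940 lower with kept libraries. The count was 701 with all libraries, 1121 without the library labelled PEA1 untreated replicate 3 and 343 without PEA1 untreated replicate 2.

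In the PEO1 and PEO4 pair, interferon-stimulated and Müllerian genes were higher in the resistant line. IFI27, an interferon-induced gene, was listed at 0 in all 3 PEO1 libraries and stood at 383, 396 and 631 rescaled TPM in PEO4 (adjusted p = 1.75e-06). BST2, which encodes the antiviral protein tetherin, was likewise listed at 0 in PEO1 and stood at 129, 125 and 160 in PEO4 (adjusted p = 0.000689). MX1, an antiviral GTPase, was higher by 4.45 ± 0.91 (adjusted p = 0.000917). Of 36 interferon-stimulated genes 11 were higher, 25 did not pass, and 17 were higher adjusted over the list alone (adjusted p = 1.5e-14, and adjusted p = 0.31 with an estimated correlation). Kept libraries gave 30 of 36 higher (31 adjusted over the list alone; adjusted p = 0.00351 with an estimated correlation). Among 16 Müllerian and serous ovarian genes 6 were higher and 10 did not pass, with 7 adjusted over the list alone (median 2.08, adjusted p = 9.26e-13, adjusted p = 0.00478 with an estimated correlation). Examples were the retinoic acid binding protein CRABP2 (7.09 ± 1.30, adjusted p = 0.00019) and MUC16, which encodes CA125 (4.23 ± 0.97, adjusted p = 0.00359). PEO4 held far less of the insulin-like growth factor binding proteins IGFBP3, with a difference of -7.60 ± 1.06, and IGFBP5, with -6.27 ± 0.58, and KISS1 was listed at 0 in PEO4 and at 30, 88.9 and 139 in PEO1. SNCG, encoding gamma-synuclein, was higher by 7.11 ± 0.95 (adjusted p = 6.08e-07). In all, 530 genes were higher and 344 lower in PEO4 and, with kept libraries, 2777 were higher and 2335 lower, although no library was removed from these 6. The model shares 1 spread per gene between all groups, so the calls here also depend on which libraries of other groups are left out. With all libraries and only the compared groups in the model the count stayed within 1.5 times. Kept libraries without rescaling gave 1974 higher and 2342 lower, so the balance of directions turned with the scaling.

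The PEO14 and PEO23 comparison rested on the 3 untreated PEO23 libraries with few genes, of which 2 resembled another line more than PEO23, and its calls are values of those libraries. S100A11, a calcium-binding protein, was lower by 7.08 ± 1.31 on the fitted scale, but its values in PEO23 were 717, 0 and 0 rescaled TPM against 1410, 1480 and 852 in PEO14. CTGF and ID3 were listed at 0 in all 3 PEO23 libraries. MTRNR2L2, a nuclear gene nearly identical to mitochondrial ribosomal RNA and therefore uncertain, stood at 2640, 39700 and 21600 in PEO23 against 2.07, 51.1 and 11.8 in PEO14. The model called 228 genes higher and 6718 lower, and 4975 to 9822 genes in all when 1 of the 6 libraries was left out; the kept libraries give no such comparison. Histones (28 of 55 lower, 29 adjusted over the list alone) and epithelial markers (16 of 22 lower, 18 adjusted over the list alone) were called lower beside the low number of genes, each with adjusted p = 0.0334 and adjusted p = 0.979 with an estimated correlation.

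Only ADAM19, a membrane metalloprotease, and NHSL2 were called in the same direction in all 3 pairs, lower in each resistant line. Both lie below the level set for named genes and were chosen after their values were seen. ADAM19 differed by -1.94, -2.62 and -1.28 in the PEA, PEO1 and PEO4, and PEO14 and PEO23 pairs (adjusted p = 0.019, 0.00047 and 0.044), and NHSL2 by -1.81, -2.86 and -3.3 (adjusted p = 0.04, 0.00021 and 1.1e-05). Independent lists of the same sizes would share 1.14 lower genes. Leaving out replicate 3 of every group gave 7 such genes, and leaving out replicate 1 or replicate 2 gave 0.

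Because the untreated PEO23 libraries were poor, resistant and sensitive lines were also compared among kept libraries after 8 h of carboplatin, a comparison chosen after seeing the data. It had 3 PEA1 and 2 PEA2 libraries, 2 PEO1 and 2 PEO4 libraries, and 3 PEO14 and 3 PEO23 libraries. In all 3 pairs 23 genes were higher and 35 lower in the resistant line, against 5.15 and 5.44 for independent lists. Opposite calls were also more than independent lists would share in 2 of the 3 sets of 2 pairs, 311 against 145 for PEA2 and PEO4 (203 in the same direction), 269 against 218 for PEA2 and PEO23 (426) and 126 against 132 for PEO4 and PEO23 (355), so an excess over independent lists does not by itself show a shared resistant direction. Interferon-stimulated genes were among the higher ones. IFIH1, the RNA sensor MDA5, was higher by 2.32 ± 0.58, 2.19 ± 0.64 and 2.66 ± 0.52 (adjusted p = 0.00448, 0.0235 and 0.000508), and OAS3, an antiviral oligoadenylate synthetase, by 1.27 ± 0.35, 2.30 ± 0.39 and 2.27 ± 0.32. Of the 36 interferon-stimulated genes 11, 30 and 22 were higher and 1, 0 and 1 lower, with adjusted p = 0.319, 8.48e-05 and 0.0257 with an estimated correlation. Adjusted over the list alone, 11, 32 and 22 were higher. CLDN3, a tight junction claudin, was higher by 4.94, 2.19 and 5.64, and the long noncoding RNA UCA1 by 6.84, 2.46 and 2.69. VIM was lower by a log2 change of -5.01, -3.03 and -4.39, the extracellular matrix gene CCDC80 by -3.82, -2.60 and -2.54, and the actin crosslinker FLNC by -3.77, -1.93 and -2.51. Untreated kept libraries of the first 2 pairs differed in the same directions for CLDN3 (3.78 and 1.93) and VIM (-4.15 and -1.31), with 1 untreated PEA1 library. At 24 h, 34 genes were higher and 19 lower in all 3 pairs, and VIM differed by 0.30 in the PEO1 and PEO4 pair (adjusted p = 0.881), where PEO4 had 1 kept library. Calls at 8 h in single pairs numbered 1618 higher and 1294 lower in PEA2, 840 and 945 in PEO4, and 1230 and 1443 in PEO23. Without rescaling they were 236 higher and 190 lower in PEO4, where the balance of directions turned, and 291 higher and 2697 lower in PEO23.

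**Figure D2:**
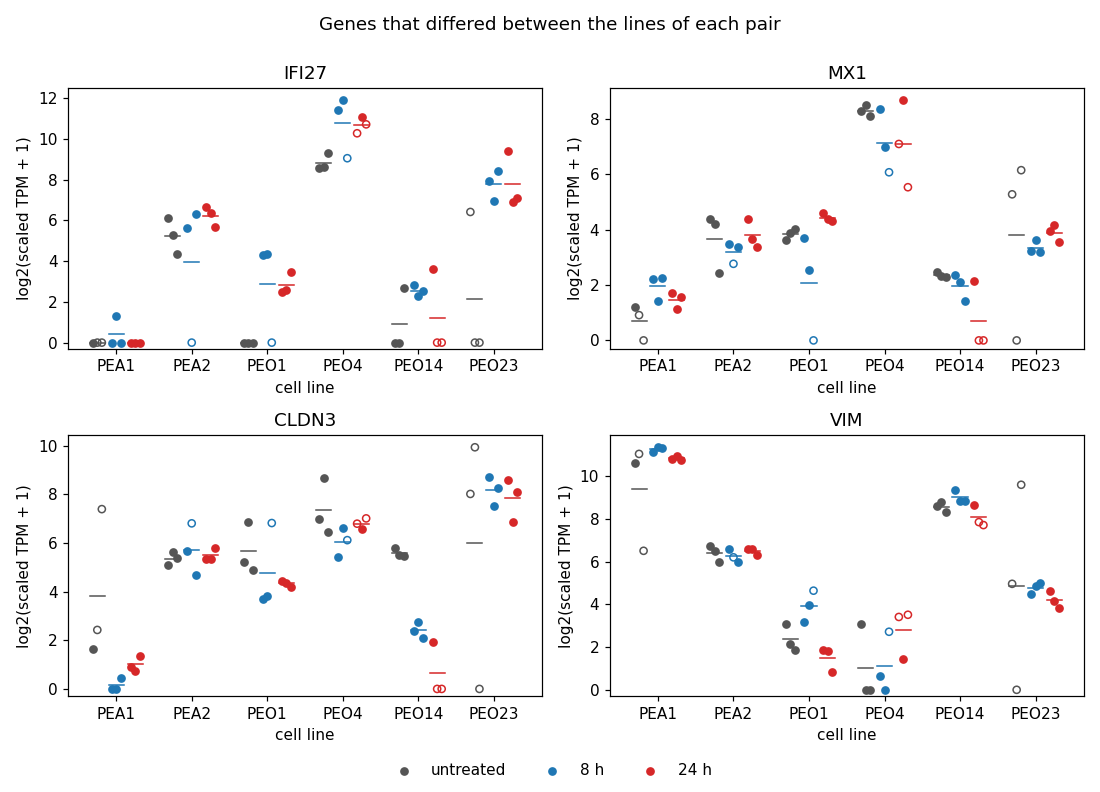
Level of IFI27, MX1, CLDN3 and VIM (y axis, log2 of rescaled TPM + 1) in each library by cell line (x axis), untreated in grey, 8 h in blue and 24 h in red. Filled points are kept libraries, open points the 12 libraries with few genes and short lines the means of 3 libraries; in PEO1 untreated libraries IFI27 was listed at 0, and in PEO4 it stood at 383 to 631 rescaled TPM.

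The series title concerns CPT1A, the carnitine palmitoyltransferase that starts mitochondrial fatty acid oxidation, so this gene and genes with known roles in platinum response were followed in every comparison. Untreated CPT1A stood at 0.646, 0 and 0 rescaled TPM in PEA1 and at 4.38, 4.52 and 9.11 in PEA2, a difference of 2.50 ± 0.90 (adjusted p = 0.125). In PEO1 it stood at 18.2, 20.4 and 18.2 and in PEO4 at 35.1, 41.9 and 24.8 (0.78 ± 0.90, adjusted p = 0.869). In kept libraries CPT1A was higher in PEA2 by 2.09 ± 0.47 (adjusted p = 0.00215, 1 PEA1 library) and in PEO4 by 1.00 ± 0.33 (adjusted p = 0.0221). At 8 h the kept libraries gave 2.52 ± 0.37 in the PEA pair (adjusted p = 5.48e-06), 0.91 ± 0.40 in the PEO1 and PEO4 pair (adjusted p = 0.178) and -1.58 ± 0.33 in the PEO14 and PEO23 pair (adjusted p = 0.00108), so PEO23 held less CPT1A than PEO14. CPT1A was not called after carboplatin at either time, in any of the 6 lines with all libraries or any of the 5 that kept untreated libraries. The 36 tested fatty acid oxidation genes were not called as a list in any untreated pair. After carboplatin the list was called higher in PEA1 at 8 h and 24 h, PEO1 at 24 h and PEO23 at 8 h and 24 h (adjusted p = 0.00286, 0.0106, 0.042, 0.022 and 0.00979), and none of these calls held with an estimated correlation (lowest adjusted p = 0.581 with an estimated correlation).

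CDKN1A, the cell cycle inhibitor p21, was called after carboplatin in PEO23 alone, by 3.02 ± 0.89 at 8 h, against the untreated libraries with few genes. MDM2, a ubiquitin ligase, rose in PEO1 at 24 h by 0.82 ± 0.30 and fell in PEO14 at 8 h by 1.05 ± 0.30 in kept libraries (adjusted p = 0.0285 and 0.00709). CCNE1, encoding cyclin E1, was higher in PEO4 at 24 h by 2.85 ± 0.57 (adjusted p = 0.000767; 2.62 ± 0.66 with 1 kept library). The copper transporter ATP7B fell in PEO14 at 24 h by 1.82 ± 0.46 (adjusted p = 0.0047), and SLC31A1, the copper transporter CTR1, rose in PEO1 at 8 h by 1.27 ± 0.34 in kept libraries (adjusted p = 0.0029). The median change of all genes in that PEO1 comparison was -0.155 with rescaling and -1.144 without it, so the size of the SLC31A1 rise depends on the scaling. ERCC1, a nucleotide excision repair nuclease, fell in PEO4 at 8 h by 1.64 ± 0.44, and ATP7A rose there by 0.92 ± 0.31, with kept libraries. In that comparison the median change of all genes was -0.235 with rescaling and -1.124 without it, so the rise of ATP7A may depend on the scaling. BRCA1 was lower in untreated PEO4 than in PEO1 by a log2 difference of -1.12 ± 0.31 with kept libraries and was not called after carboplatin, and BRCA2 was called after carboplatin only in PEO23 (1.68 at 8 h, adjusted p = 0.0496). ABCB1, the drug efflux pump, was listed at 0 in all libraries except 4, where it reached 0.305 rescaled TPM, and was not tested.

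After 8 h of carboplatin 13 genes were lower than in untreated cells in all 6 lines, where independent lists of the same sizes would share 3.97e-05. Among them were the transcription factor ZNF750, which changed by -4.03, -4.32, -5.32, -4.05, -4.04 and -4.71 in PEA1, PEA2, PEO1, PEO4, PEO14 and PEO23 (SE 0.80, highest adjusted p = 0.00262), and the transcription factor ZFHX3, with -2.94, -2.59, -2.62, -2.35, -2.86 and -2.59 (SE 0.59, highest adjusted p = 0.00835). The nuclear noncoding RNA KCNQ1OT1 changed by -1.93 to -3.97 (SE 0.56). BTBD9, NFIC, PSAPL1 and SMCR5 fell too, while SPDYE2, SPDYE2B, SPDYE5 and NUTM2B have near-identical copies and COL18A1-AS1, ITPK1-AS1 and KCNQ1OT1 lie antisense to other genes, so these 7 are uncertain. Leaving out replicate 3 of every group gave 37 such genes, replicate 1 gave 1 and replicate 2 gave 0. A pseudocount of 0.1 gave 3, and limma with only the compared groups in the model gave 0. In kept libraries of the 5 lines other than PEO23, 547 genes fell and 38 rose in every line. The nuclear noncoding RNAs MALAT1 and NEAT1, chosen after their values were seen, were among those that fell. MALAT1 changed by -4.18, -2.53, -3.98, -3.52 and -4.11 in PEA1, PEA2, PEO1, PEO4 and PEO14, and NEAT1 by -4.27, -3.47, -6.09, -5.11 and -5.61 (highest adjusted p = 6.49e-05 and 3.78e-05). NFKBIA, the NF-kB inhibitor, rose by 1.30, 0.77, 0.88, 0.58 and 0.99 in the same 5 lines. The glycolytic enzyme ENO1 rose by 0.97, 0.65, 1.34 and 1.10 in PEA1, PEA2, PEO1 and PEO14, and it also rose in PEO4 (adjusted p = 1.68e-08). Both genes were chosen after their values were seen. In these libraries the median change of all genes was -0.155 in PEO1 and -0.235 in PEO4 with rescaling, and -1.144 and -1.124 without it. Rises of this size in PEO1 and PEO4 may therefore depend on the scaling.

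Camera called ribosomal protein genes higher in all 6 lines at 8 h at the preset correlation and in none with an estimated correlation (lowest adjusted p = 0.581). Their median change in PEO1 was 2.06, with 4 of 74 called higher (5 adjusted over the list alone), among them RPL26 (2.89 ± 0.88) and RPL27A (2.88 ± 0.78). In PEO4 it was 2.57 with 12 called higher (29 adjusted over the list alone). Camera gave adjusted p = 5.61e-18 and 9.14e-19, and adjusted p = 0.946 and 0.802 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes followed the same direction, with 9 of 77 higher in PEO4 (26 adjusted over the list alone), among them NDUFB2 and ATP5F1, and replication-dependent histones had 10 of 55 higher there (31 adjusted over the list alone), including HIST1H2AD. In kept libraries of PEO1, 72 of 74 ribosomal protein genes and 70 of 77 oxidative phosphorylation genes were higher (72 and 71 adjusted over each list alone; adjusted p = 0.233 and 0.137 with an estimated correlation). Without rescaling the ribosomal medians in PEO1 and PEO4 were 0.26 and 0.68, and the median of oxidative phosphorylation genes in PEO1 was -0.05. The lipogenic enzyme FASN changed in PEO1 and PEO4 by -3.03 ± 0.89 and -3.68 ± 0.89 (adjusted p = 0.0392 and 0.00583), and its regulator SREBF1 fell by 2.13 ± 0.64 and 2.38 ± 0.64. These mRNAs and NEAT1 moved together with the share of the library that ribosomal protein mRNA took, a median of 11.7% in untreated and 18.8% in treated kept libraries.

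Calls at 8 h with all libraries numbered 150 higher and 330 lower in PEA1, 16 and 562 in PEA2, 124 and 697 in PEO1, 496 and 1355 in PEO4, 14 and 937 in PEO14, and 6007 and 491 in PEO23. In PEO23 the untreated libraries were those with few genes. Kept libraries gave 109 higher and 953 lower in PEA1, 633 and 1935 in PEA2, 3141 and 4406 in PEO1, 3888 and 5756 in PEO4, and 1599 and 3805 in PEO14. Without rescaling, the median change of all genes was -1.208 in PEO1, -1.087 in PEO4, -0.59 in PEO14, -0.448 in PEA2 and 0.425 in PEO23, against -0.137, 0, -0.088, -0.076 and 1.173 with it. The calls were then 27 higher and 4377 lower in PEO1, 97 and 4832 in PEO4, and 2109 and 684 in PEO23, and for kept libraries 386 and 8529 in PEO1, 1141 and 8560 in PEO4, 280 and 5268 in PEO14, and 134 and 2638 in PEA2. In kept libraries of PEA1, with 1 untreated library, the median change of all genes was -0.328 without rescaling and 0 with it. Leaving out PEA1 untreated replicate 1 raised the PEA1 count from 480 to 1499, leaving out PEO4 8 h replicate 3 raised the PEO4 count from 1851 to 3058, and leaving out PEO1 untreated replicate 2 lowered the PEO1 count from 821 to 333.

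**Figure D3:**
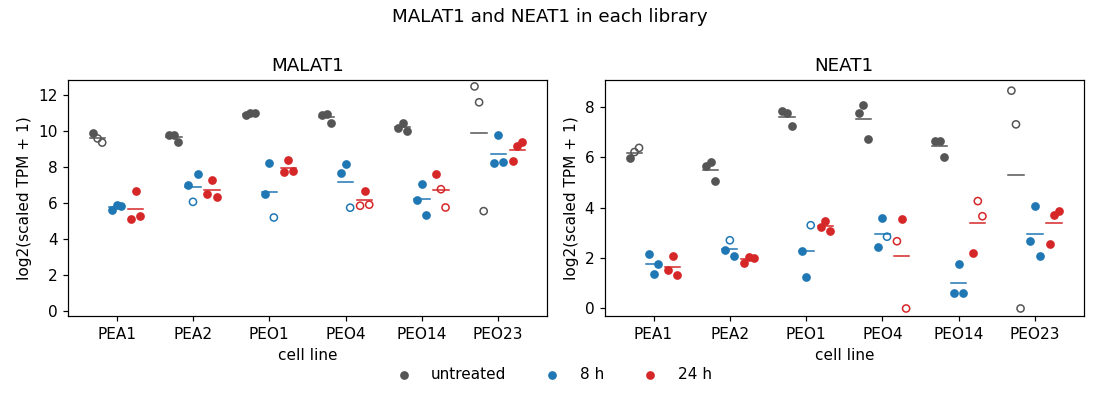
Level of the nuclear noncoding RNAs MALAT1 and NEAT1 (y axis, log2 of rescaled TPM + 1) in each library by cell line (x axis), untreated in grey, 8 h in blue and 24 h in red. Filled points are kept libraries, open points the 12 libraries with few genes and short lines the means of 3 libraries; MALAT1 in PEO1 went from 1900, 2020 and 2010 rescaled TPM untreated to 89.9, 292 and 35.3 at 8 h.

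After 24 h of carboplatin 12 genes were lower in all 6 lines, against 6.35e-05 for independent lists. Leaving out replicate 3 of every group gave 22 such genes, replicate 1 gave 1 and replicate 2 gave 0, a pseudocount of 0.1 gave 2, and limma with only the compared groups in the model gave 0. ZNF750 changed by -3.87, -4.07, -4.86, -3.34, -4.73 and -4.95 and ZFHX3 by -2.87, -2.48, -3.29, -2.47, -2.15 and -2.46 in PEA1, PEA2, PEO1, PEO4, PEO14 and PEO23. BTBD9 and NOL4L also fell in all 6 lines. RPA3, a subunit of the single-stranded DNA binding complex RPA, was higher in 5 lines, by 3.70 ± 0.91 in PEA1, 3.37 in PEO1, 2.88 in PEO4, 3.11 in PEO14 and 5.09 in PEO23, and by 1.90 in PEA2, where it did not pass (adjusted p = 0.546). With kept libraries RPA3 was called in PEA2, PEO1 and PEO14 and gave 1.45 in PEA1 and 1.39 in PEO4 (adjusted p = 0.382 and 0.247). In PEO1 the cytokines CXCL8, or interleukin 8, and IL6, interleukin 6, were among the genes that rose most. CXCL8 went from 1.89, 0.611 and 2.22 to 183, 132 and 127 rescaled TPM (5.89 ± 1.18, adjusted p = 0.00186), and IL6 from 2.81, 0 and 8.26 to 143, 114 and 155 (5.39 ± 1.35, adjusted p = 0.0148). Of 29 NF-kB and cytokine genes 5 were higher in PEO1 and 24 did not pass (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.000507, and adjusted p = 0.624 with an estimated correlation). CXCL8 rose in kept libraries also in PEA2 by 2.03 and in PEO14 by 3.07. FASN fell by 4.18 ± 0.89 in PEO4 and fell by 3.21 ± 0.89 in PEO14.

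Ribosomal protein medians at 24 h were 1.41, 1.17, 1.65, 1.38, 1.96 and 5.20 in PEA1, PEA2, PEO1, PEO4, PEO14 and PEO23. NRF2 targets, which include antioxidant enzymes, were higher as a list in kept libraries of PEA2 (adjusted p = 0.00838 by camera with an estimated correlation). The list was also higher in kept libraries of PEA1, PEO4 and PEO14. These 3 comparisons each had 1 kept library in a group, untreated PEA1, PEO4 at 24 h and PEO14 at 24 h. The list median was -0.25 in PEO14 without rescaling, where all genes had a median of -1.116. Calls numbered 113 higher and 303 lower in PEA1, 13 and 400 in PEA2, 50 and 564 in PEO1, 527 and 1512 in PEO4, 219 and 2667 in PEO14, and 6049 and 468 in PEO23. With kept libraries they were 142 and 941, 856 and 2251, 2827 and 4128, 1308 and 2289, and 2424 and 4085 in the first 5 lines. Without rescaling the median change of all genes was -0.328 in PEA2, -0.459 in PEO1, -1.026 in PEO4 and -1.555 in PEO14, against 0, 0, -0.322 and -0.619 with it. PEO4 then gave 160 and 3591, PEO14 32 and 7029 and PEO23 2780 and 613, and kept libraries gave 1045 and 5333 in PEO1, 486 and 2614 in PEO4, 298 and 6826 in PEO14, 147 and 3147 in PEA2 and 44 and 1457 in PEA1. Leaving out PEA1 untreated replicate 1 raised the PEA1 count from 416 to 1246, leaving out PEO4 24 h replicate 2 raised the PEO4 count from 2039 to 3094, and leaving out PEO14 24 h replicate 2 lowered the PEO14 count from 2886 to 1156.

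How the response went on between 8 h and 24 h was tested within each line, and few genes passed with all libraries. In PEA1, FPR1 rose by 1.01 (adjusted p = 0.00065), and ZEB2-AS1, an antisense gene and so uncertain, was listed at 0 at 8 h and at 5.52, 3.70 and 8.62 rescaled TPM at 24 h. In PEO1, DMRT2 rose by 1.65, NR0B1 by 1.63, GGT3P by 1.28 and PCYT1B by 1.12, and LOC101929532 fell by 1.92. FPR1 and the 5 PEO1 genes were chosen after their values were seen. With the replicate number as a block over the 8 h and 24 h libraries, limma called 0 genes in PEO1, where 1075 had an unadjusted p under 0.05. In PEO14, CGA, the common alpha subunit of glycoprotein hormones, was listed above 0 in all 3 libraries at 8 h and at 0 in all 3 at 24 h (adjusted p = 5.6e-05), but 2 of the 3 at 24 h were libraries listing few genes, where a 0 is common. The kept libraries hold 1 PEO14 library at 24 h, and the block there compares 1 library with 1, so they give no check of CGA on replicates. With kept libraries, 2 at 8 h and 3 at 24 h, PEO1 showed more. TXNIP, which binds thioredoxin and restrains glucose uptake, rose by 3.12 ± 0.31 (adjusted p = 1.07e-06), the stress-induced transcription factor ATF3 by 2.38 ± 0.44, the NF-kB inhibitor TNFAIP3 by 2.77 ± 0.41 and GADD45A by 1.87 ± 0.37, while the mitotic genes CCNB1 and CDC20 fell by 1.95 ± 0.36 and 1.79 ± 0.23. Of 41 G2/M and mitosis genes 10 were lower and 31 did not pass (17 adjusted over the list alone; median -0.70, adjusted p = 0.0345 with an estimated correlation), but without rescaling their median was 0.44, and with the block over the 8 h and 24 h libraries 3 were lower (adjusted p = 0.0457 with an estimated correlation). Of 29 NF-kB and cytokine genes 2 were higher (8 adjusted over the list alone; median 0.74, adjusted p = 9.21e-05 with an estimated correlation), and 1 was higher with the block. TXNIP, ATF3, GADD45A, CCNB1 and CDC20 were chosen after their values were seen. With the block ATF3 and GADD45A did not pass (adjusted p = 0.208 and 0.318), and the other 4 named genes did. In these kept libraries the median change of all genes was 0 with rescaling and 0.619 without it. The sizes of the named rises and falls in PEO1 therefore depend on the scaling, which the block does not test.

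Replication-dependent histones were lower at 24 h than at 8 h in 5 lines with all libraries, by a median of -0.75 in PEA1, -0.50 in PEA2, -0.97 in PEO1, -1.42 in PEO4 and -1.37 in PEO23 (adjusted p = 6.47e-16, 2.17e-07, 2.12e-08, 1.65e-05 and 2.15e-22). None of these 5 calls held with an estimated correlation, which gave adjusted p = 0.444 in PEA1 and 0.313 in PEO23, and the PEO1 median was -0.02 without rescaling. With kept libraries and the block the list was lower in PEO1 and PEO23 (median -1.38 and -1.39, adjusted p = 0.0457 and 0.0403 with an estimated correlation, against 0.0731 and 0.0735 without the block). In the other 4 lines it was lower at the preset correlation only, and no difference between lines was tested. Genes called numbered 2 higher and 0 lower in PEA1, 4 and 1 in PEO1, 74 and 76 in PEO4, 13 and 141 in PEO14, and 4 and 7 in PEO23, and limma called 0 genes in PEA2, where 190 had an unadjusted p under 0.05. With kept libraries they were 4 and 1 in PEA1, 17 and 22 in PEO1, 1378 and 1158 in PEO4, 95 and 360 in PEO14, 14 and 57 in PEO23, and 0 in PEA2 by limma, with 259 at an unadjusted p under 0.05. With kept libraries and the block they were 1 and 1 in PEA1, 4 and 9 in PEO1 and 4 and 20 in PEO23. In PEO4 and PEO14 that fit compares 1 library with 1, so no counts are given. Without rescaling PEO1 gave 17 and 0, PEO4 38 and 3, and PEO23 0 and 2, and kept libraries gave 161 and 2 in PEO1, 2322 and 85 in PEO4, 4 and 253 in PEO14, and 0 and 1 in PEO23. The PEO1 count moved from 5 to 35 without PEO1 8 h replicate 2 and to 1 without PEO1 8 h replicate 3. Leaving out PEO4 8 h replicate 3 moved the PEO4 count from 150 to 1535, and leaving out PEO14 24 h replicate 1 moved the PEO14 count from 154 to 2469.

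**Figure D4:**
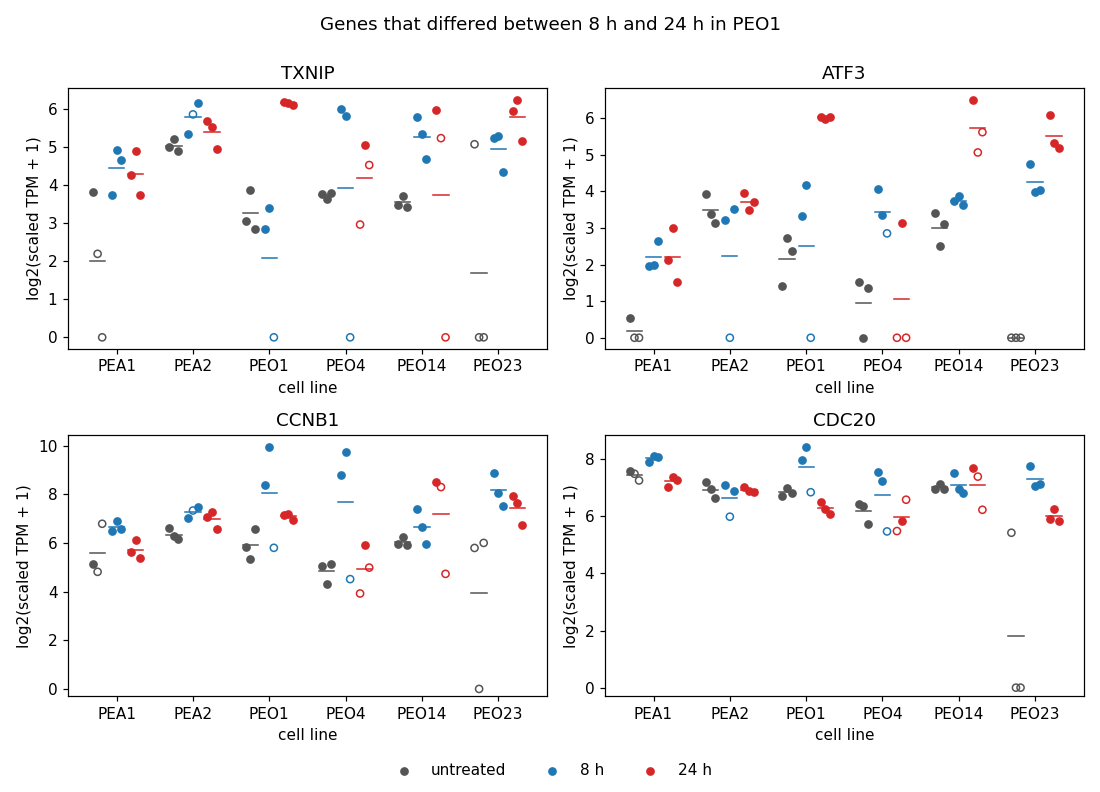
Level of TXNIP, ATF3, CCNB1 and CDC20 (y axis, log2 of rescaled TPM + 1) in each library by cell line (x axis), untreated in grey, 8 h in blue and 24 h in red, for genes called between 8 h and 24 h in PEO1 with kept libraries. Filled points are kept libraries, open points the 12 libraries with few genes and short lines the means of 3 libraries; TXNIP in PEO1 stood at 72, 71.2 and 68.1 rescaled TPM at 24 h.

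Whether resistant and sensitive lines responded differently was tested as the difference of their changes. In the PEA pair the response at 8 h differed for 27 genes, 3 with a higher change in PEA2 and 24 with a lower one. RPE65, a retinoid isomerase, was listed at 0 in all 9 PEA1 libraries and went from 13.8, 21.4 and 28.2 rescaled TPM in untreated PEA2 to 1.1, 0 and 0 at 8 h (adjusted p = 2.27e-12). Since RPE65 could not fall from 0 in PEA1, its difference is the fall in PEA2 and does not compare the responses. JSRP1 differed by 4.83 ± 0.96, but PEA1 untreated libraries stood at 0.791, 24.6 and 115, and with kept libraries the difference was 0.92 ± 0.75 (adjusted p = 1). In the PEO1 and PEO4 pair 11 genes had a higher and 41 a lower change in PEO4 at 8 h. FAM101A, a filamin-interacting protein, fell in PEO4 from 112, 97.5 and 132 to 0, 2.73 and 22.1 and in PEO1 stood at 0, 1.44 and 0 untreated, a difference of -4.26 ± 0.88 (adjusted p = 0.0107; -5.88 ± 0.60 with kept libraries). From that level FAM101A could hardly fall in PEO1, so a like response there could not have been seen. S100A5, a calcium-binding protein, rose in PEO4 and had a change higher by 4.17 ± 0.84 than in PEO1 (adjusted p = 0.00768). MUC16 changed by -3.43 in PEO1 and by -5.82 in PEO4 at 8 h, and the difference was -2.35 ± 0.55 with kept libraries (adjusted p = 0.0162). TEN1, a telomere-capping subunit, differed at 24 h by 8.00 ± 1.62 (adjusted p = 0.00729), from 0, 0 and 2 in untreated PEO4 to 562, 115 and 1070, and by 6.72 ± 0.95 with 1 kept library of PEO4 at 24 h, which held 115. Epithelial markers had a higher change in PEA2 at 8 h (median 1.51, adjusted p = 3.56e-07, adjusted p = 1.0 with an estimated correlation), in a comparison against the library labelled PEA1 untreated replicate 3.

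At 24 h the differences numbered 1 higher and 21 lower in the PEA pair and 19 and 41 in the PEO1 and PEO4 pair. Kept libraries gave 30 and 31 at 8 h and 30 and 39 at 24 h in the PEA pair, and 132 and 291 at 8 h and 96 and 153 at 24 h in the PEO1 and PEO4 pair. Without rescaling the PEO1 and PEO4 pair gave 41 higher and 85 lower at 8 h. For PEO23 minus PEO14 the model called 2327 higher and 40 lower at 8 h and 6072 and 71 at 24 h, which include the histones HIST1H3G and HIST1H4J and the uncertain MTRNR2L2, and all rest on untreated PEO23 libraries with few genes. Removal of PEA1 untreated replicate 1 raised the PEA counts from 27 to 123 at 8 h and from 22 to 92 at 24 h. Removal of PEO4 untreated replicate 3 raised the count for PEO4 from 52 to 99 at 8 h, and removal of PEO4 24 h replicate 2 raised it from 60 to 430 at 24 h.

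Over the 27 planned comparisons with all libraries, 33 gene lists were tested with camera, which made 138 calls higher and 29 lower at a preset correlation of 0.01. With an estimated correlation 1 of these 167 calls held, the Müllerian and serous ovarian list in untreated PEO4. Among the lists, cytosolic ribosomal proteins were called higher in 14 and lower in 4 comparisons, replication-dependent histones in 14 and 6, and oxidative phosphorylation genes in 13 and 1. G1/S and DNA replication genes were higher in 10. Epithelial markers were higher in 7 and lower in 3, heat shock genes in 7 and 1, integrated stress response genes in 7 and 1, and unfolded protein response genes in 7 and 0. Interferon-stimulated genes and NRF2 targets were each higher in 6, metallothioneins were higher in 6 and lower in 2, and NF-kB and cytokine genes were higher in 5 and lower in 1. Fatty acid oxidation and cholesterol synthesis genes were each higher in 5. G2/M and mitosis genes were higher in 4 and lower in 4, small structural RNAs in 4 and 1, and glycolysis genes in 3 and 1. Homologous recombination genes and glutathione transferases were each higher in 3. Hypoxia, immediate early, mismatch repair and Müllerian genes were each higher in 1, and the Fanconi anaemia, mesenchymal, fibroblast and endothelial lists were each lower in 1, the endothelial list between 8 h and 24 h in PEO14 (adjusted p = 0.0406, and 0.069 with the replicate block). Camera did not call the BCL2 family, fatty acid synthesis, nucleotide excision repair, platinum and drug transport or leukocyte marker lists in any of these comparisons. Kept libraries gave 178 calls higher and 46 lower, of which 23 of 224 held with an estimated correlation.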

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

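Of the tests given here, the fits without the 12 libraries that listed few genes were chosen only after the results were seen. What singled out the genes was limma's test of the difference between the responses of the 2 lines of a pair, the resistant minus the sensitive line, with 3 libraries per group. A fitted difference of a gene listed at 0 in a group depends on the pseudocount and bounds no fold. A gene at or near 0 in the sensitive line cannot fall there, so a lower change in the resistant line shows no different response.

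In the PEA pair 27 genes differed at 8 h. JSRP1 had a difference of 4.83, C2orf27A of 4.64 and DSCR8 of 2.24, and RPE65, PSG10P, PSG11 and LOC101927023 had -4.06, -4.01, -3.97 and -3.96. At 24 h 22 genes differed, with JSRP1 at 4.59, PSG10P at -3.89, RPE65 at -3.86, PSG5 at -3.78 and LOC101928744 at -3.72. The PSG genes are near-identical copies of each other and uncertain. Of 100 splits of the libraries 9 called as many genes at 8 h, with 386 in the highest other, and 8 did so at 24 h, with 281 in the highest other, so chance was not excluded for either count. Treated and untreated libraries were exchanged within each line separately. A split that exchanges them in a single line turns a change shared by both lines into a difference. High counts in other splits can arise in this way, so these splits cannot decide on chance.

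In the PEO1 and PEO4 pair 52 genes differed at 8 h. S100A5 had a difference of 4.17, C1orf105 of 2.97, TBX10 of 2.93 and GGT8P of 2.59, and FAM101A, GOLGA6L7P, MBD3L1 and CCR10 had -4.26, -4.17, -4.08 and -3.98. GOLGA6L7P was listed at 0 in all 9 PEO1 libraries and, after carboplatin, in all 6 PEO4 libraries, and stood at 13, 12.4 and 30 rescaled TPM in untreated PEO4. It could not fall in PEO1, so its difference is the fall in PEO4. At 24 h 60 genes differed, with TEN1 at 8.00, LINC00880 at 5.50, THRB-AS1 at 5.21, SLC25A21-AS1 at 4.88, LOC102723590 at -5.10, FAM101A at -4.76, GOLGA6L7P at -4.17 and C9orf9 at -3.96. The antisense genes and the pseudogenes GGT8P and GOLGA6L7P are uncertain. SLC25A21-AS1 stood at 82.5, 11.3 and 281 rescaled TPM in PEO4 at 24 h, the first and last in libraries with few genes, and without the 12 libraries its difference was 2.73 ± 1.00 (adjusted p = 0.205). Of 100 splits 20 called as many genes at 8 h, with 3209 in the highest other, and 12 did so at 24 h, with 681 in the highest other. Chance was not excluded for either, and the splits cannot decide on it. As in the PEA pair, an exchange within a single line can turn a shared change into a difference.

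In the PEO14 and PEO23 pair 2367 genes differed at 8 h and 6143 at 24 h, with the 3 untreated PEO23 libraries that listed 11151, 2678 and 2985 genes in every comparison. At 8 h CRIP1 had a difference of 8.88, HIST1H3G of 8.86, HIST1H4J of 8.58, HIST1H2AJ of 8.49, MTRNR2L2 of -9.41, MTRNR2L8 of -7.48, MTRNR2L9 of -6.97 and MTRNR2L1 of -6.70. At 24 h RPL21 had 12.40, HIST1H4J 12.23, COX17 10.94, HIST1H2BN 9.45, MTRNR2L2 -11.80, MTRNR2L8 -10.07, MTRNR2L1 -8.95 and MTRNR2L9 -8.82. The MTRNR2L genes, the histones and RPL21 share near-identical sequence with other genes and are uncertain. Of 100 splits 3 called as many genes at 8 h, with 3356 in the highest other, and 1 did so at 24 h, the real one, with 5250 in the highest other. The share of splits as large was under 0.05 at both times. The real split, however, keeps the 3 untreated PEO23 libraries with few genes together. The splits therefore cannot tell a difference in response from the few genes listed in those libraries. The highest split at 8 h can also come from an exchange of treated and untreated libraries in a single line.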

How the results depend on the processing

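The settings without the 12 libraries that listed few genes, with the 8 h libraries of the same lines and with a replicate block over the 8 h and 24 h libraries were chosen only after the results were seen. Counts that moved by over 1.5 times are given for each setting, and for them the cause was not tested unless a reason is given. With the main settings the counts were 701 in PEA2, 874 in PEO4 and 6946 in PEO23 for the resistant line without drug, 480 in PEA1, 578 in PEA2, 821 in PEO1, 1851 in PEO4, 951 in PEO14 and 6498 in PEO23 after 8 h, and 416 in PEA1, 413 in PEA2, 614 in PEO1, 2039 in PEO4, 2886 in PEO14 and 6517 in PEO23 after 24 h. They were 2 in PEA1, 0 in PEA2, 5 in PEO1, 150 in PEO4, 154 in PEO14 and 11 in PEO23 between 8 h and 24 h, 27 in PEA2, 52 in PEO4 and 2367 in PEO23 for the response difference at 8 h, 22 in PEA2, 60 in PEO4 and 6143 in PEO23 for the response difference at 24 h, and 2 in all 3 pairs without drug, 13 in all 6 lines at 8 h and 12 in all 6 lines at 24 h for genes called in every group. These are genes called by limma, and gene lists called by camera numbered 167.

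With a pseudocount of 0.1 the counts were 140 in PEA1, 369 in PEA2, 464 in PEO1, 879 in PEO4 and 623 in PEO14 after 8 h, 117 in PEA1, 174 in PEA2, 257 in PEO1 and 1300 in PEO4 after 24 h, and 2 in PEO1, 79 in PEO4 and 5 in PEO23 between 8 h and 24 h. They were 15 in PEA2, 18 in PEO4 and 3933 in PEO23 for the response difference at 8 h, 13 in PEA2, 22 in PEO4 and 9241 in PEO23 for the response difference at 24 h, and 0 in all 3 pairs without drug, 3 in all 6 lines at 8 h and 2 in all 6 lines at 24 h for genes called in every group. The other 9 counts stayed within 1.5 times. Without a filter on low values the counts were 8 in PEA1, 5 in PEA2, 22 in PEO1 and 30 in PEO23 between 8 h and 24 h, 51 in PEA2 and 83 in PEO4 for the response difference at 8 h, and 48 in PEA2 for the response difference at 24 h. The other 23 stayed within 1.5 times. With the replicate number as a block the counts were 12 higher and 90 lower, rounded 1.0e+02, in PEO14 and 7 in PEO23 between 8 h and 24 h, and 1 in all 3 pairs without drug for genes called in every group. The other 27 stayed within 1.5 times.

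With TPM as deposited the counts were 1329 in PEA2 for the resistant line without drug, 737 in PEA1, 1271 in PEA2, 4404 in PEO1, 4929 in PEO4, 2073 in PEO14 and 2793 in PEO23 after 8 h, and 684 in PEA1, 840 in PEA2, 1633 in PEO1, 3751 in PEO4, 7061 in PEO14 and 3393 in PEO23 after 24 h. They were 17 in PEO1, 41 in PEO4, 467 in PEO14 and 2 in PEO23 between 8 h and 24 h, 65 in PEA2 and 126 in PEO4 for the response difference at 8 h, 54 in PEA2 and 93 in PEO4 for the response difference at 24 h, and 4 in all 3 pairs without drug, 47 in all 6 lines at 8 h and 34 in all 6 lines at 24 h for genes called in every group. The other 7 counts stayed within 1.5 times, among them 145 list calls.

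With only the compared groups in the model the counts were 128 in PEA2 and 4155 in PEO23 for the resistant line without drug, 14 in PEA1, 1386 in PEA2, 186 in PEO1, 14 in PEO4, 4892 in PEO14 and 2313 in PEO23 after 8 h, and 9 in PEA1, 3364 in PEA2, 6750 in PEO1, 24 in PEO4, 1618 in PEO14 and 2227 in PEO23 after 24 h. They were 0 in PEA1, 1 in PEA2, 40 in PEO1, 0 in PEO4, 14 in PEO14 and 0 in PEO23 between 8 h and 24 h, 50 in PEA2 and 33 in PEO4 for the response difference at 8 h, 61 in PEA2, 117 in PEO4 and 1803 in PEO23 for the response difference at 24 h, and 0 in all 3 pairs without drug, 0 in all 6 lines at 8 h and 0 in all 6 lines at 24 h for genes called in every group. The other 2 counts stayed within 1.5 times.

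Without the 12 libraries that listed few genes, a setting in which a lone library is assumed to vary like the other groups, the counts were 2076 in PEA2 and 5112 in PEO4 for the resistant line without drug, 1062 in PEA1, 2568 in PEA2, 7547 in PEO1, 9644 in PEO4 and 5404 in PEO14 after 8 h, and 1083 in PEA1, 3107 in PEA2, 6955 in PEO1, 3597 in PEO4 and 6509 in PEO14 after 24 h. They were 5 in PEA1, 39 in PEO1, 2536 in PEO4, 455 in PEO14 and 71 in PEO23 between 8 h and 24 h, 61 in PEA2 and 423 in PEO4 for the response difference at 8 h, and 69 in PEA2 and 249 in PEO4 for the response difference at 24 h. The PEA2 count between 8 h and 24 h, 0 genes by limma with 259 at an unadjusted p under 0.05, stayed the same. List calls rose from 134 with all libraries in the same comparisons to 224. The setting gives no count for the 8 results that need untreated PEO23. The 8 h libraries of the same lines gave 2912 in PEA2, 1785 in PEO4, 2673 in PEO23 and 58 in all 3 pairs. Requiring 5 of 6 lines gave 47 genes at 8 h and 39 at 24 h. Fewer groups had to pass in that setting and in leaving out a pair. Leaving out the PEA1 and PEA2 pair gave 147 genes called in both other pairs, leaving out PEO1 and PEO4 gave 50, and leaving out PEO14 and PEO23 gave 33, where 39 genes were called in opposite directions (14.9 for independent lists). Without the 12 libraries the same 2 pairs shared 178 higher and 145 lower genes, against 175 and 122 for independent lists, and 415 in opposite directions, against 292. With an estimated correlation 1 gene list call was left.

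Leaving out each library in turn gave these lowest and highest counts, with the library left out in brackets. The resistant line without drug gave 343 (PEA1 untreated replicate 2) to 1121 (PEA1 untreated replicate 3) in PEA2, 621 (PEO1 untreated replicate 1) to 756 (PEO4 untreated replicate 3) in PEO4 and 4975 (PEO23 untreated replicate 3) to 9822 (PEO23 untreated replicate 1) in PEO23. Treatment for 8 h gave 160 (PEA1 8 h replicate 3) to 1499 (PEA1 untreated replicate 1) in PEA1, 253 (PEA2 8 h replicate 2) to 483 (PEA2 8 h replicate 1) in PEA2, 333 (PEO1 untreated replicate 2) to 710 (PEO1 8 h replicate 3) in PEO1, 836 (PEO4 8 h replicate 2) to 3058 (PEO4 8 h replicate 3) in PEO4, 490 (PEO14 untreated replicate 3) to 629 (PEO14 untreated replicate 1) in PEO14 and 3538 (PEO23 untreated replicate 2) to 8853 (PEO23 untreated replicate 1) in PEO23. Treatment for 24 h gave 153 (PEA1 24 h replicate 2) to 1246 (PEA1 untreated replicate 1) in PEA1, 194 (PEA2 untreated replicate 3) to 310 (PEA2 untreated replicate 1) in PEA2, 266 (PEO1 24 h replicate 1) to 454 (PEO1 untreated replicate 3) in PEO1, 675 (PEO4 24 h replicate 3) to 3094 (PEO4 24 h replicate 2) in PEO4, 1156 (PEO14 24 h replicate 2) to 4574 (PEO14 24 h replicate 1) in PEO14 and 3549 (PEO23 untreated replicate 2) to 8925 (PEO23 untreated replicate 1) in PEO23. The step from 8 h to 24 h gave 1 (PEA1 24 h replicate 1) to 2 (PEA1 8 h replicate 1) in PEA1, 0 (PEA2 8 h replicate 2) to 2 (PEA2 8 h replicate 1) in PEA2, 1 (PEO1 8 h replicate 3) to 35 (PEO1 8 h replicate 2) in PEO1, 78 (PEO4 8 h replicate 2) to 1535 (PEO4 8 h replicate 3) in PEO4, 38 (PEO14 8 h replicate 1) to 2469 (PEO14 24 h replicate 1) in PEO14 and 7 (PEO23 24 h replicate 3) to 18 (PEO23 24 h replicate 1) in PEO23. The response difference at 8 h gave 22 (PEA1 8 h replicate 1) to 123 (PEA1 untreated replicate 1) in PEA2, 41 (PEO1 untreated replicate 3) to 99 (PEO4 untreated replicate 3) in PEO4 and 1232 (PEO14 8 h replicate 3) to 7022 (PEO23 untreated replicate 1) in PEO23. The response difference at 24 h gave 16 (PEA1 24 h replicate 2) to 92 (PEA1 untreated replicate 1) in PEA2, 44 (PEO1 24 h replicate 2) to 430 (PEO4 24 h replicate 2) in PEO4 and 3904 (PEO14 24 h replicate 2) to 9182 (PEO23 untreated replicate 1) in PEO23. Genes shared by groups gave 0 (replicate 1) to 7 (replicate 3) in all 3 pairs without drug, 0 (replicate 2) to 37 (replicate 3) in all 6 lines at 8 h and 0 (replicate 2) to 22 (replicate 3) in all 6 lines at 24 h. For genes shared by groups the same replicate number was left out of every group.

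The 8 h and 24 h cultures with the same line and replicate number shared a passage, and the replicate number as a block over these libraries moved the count between 8 h and 24 h to 0 in PEO1 by limma, with 1075 genes at an unadjusted p under 0.05, and to 2 in PEA1, 0 in PEA2, 196 in PEO4, 108 in PEO14 and 14 in PEO23, within 1.5 times. Without the 12 libraries that listed few genes the block gave 13 in PEO1, 2368 in PEO4, 5 in PEO14 and 24 in PEO23, against 39, 2536, 455 and 71 in those libraries without it, and 2 in PEA1 and 0 in PEA2. With all libraries the block ended the call of the endothelial list in PEO14 and changed no other list call between 8 h and 24 h. Without the 12 libraries and with an estimated correlation, the block brought under 0.05 the glycolysis, G1/S and G2/M lists in PEA1, cholesterol synthesis and histones in PEO1, and histones and NF-kB genes in PEO23, and ended the call of integrated stress genes in PEA2. For the other comparisons replicate numbers were not established to pair cultures, since passages of untreated and treated cultures overlapped in 1 of 18 cases and no comparison had correlations above 0.1 for all 3 numbers, so the block there is a setting only.

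Depth is unknown from TPM, and low values carry an unknown counting error. In simulated data with the real spread, 0% of genes changed by a log2 of 1 were called and at most 56.1% of those changed by 4, so smaller changes can be missed with all libraries. The simulation gave a gene the same spread in every library. Its shares and its false calls therefore do not carry over to libraries of unequal quality.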

Other observations

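The tests of passage, day or batch, of few genes in the library labelled PEA1 untreated replicate 3 and of libraries listing few genes and of rescaling for the interferon genes were chosen only after the result was seen, as was the model of kept libraries behind every value in this paragraph and the next. At 8 h of carboplatin several genes separated resistant from sensitive lines in kept libraries, and those named here were chosen after their values were seen. ASS1, the argininosuccinate synthetase of arginine synthesis, was higher in all 3 resistant lines, by 2.12 ± 0.40 in PEA2, 3.09 ± 0.44 in PEO4 and 4.15 ± 0.36 in PEO23 (adjusted p = 0.000195, 7.51e-06 and 8.85e-10). MSLN, the surface protein mesothelin, was listed at 0 in all 3 PEA1 libraries and at 4.10 and 7.69 rescaled TPM in PEA2, and was higher by 2.17 ± 0.52 in PEO4 and 3.45 ± 0.42 in PEO23 (adjusted p = 0.0048 and 6.63e-07). CRIP1 stood at 1920, 717 and 1910 rescaled TPM in PEO23 against 1.33, 0 and 2.56 in PEO14, and was listed at 0 in PEA1 at 8 h. The calcium-binding protein S100A9 differed by 7.39 ± 0.82 in PEO23 but by -5.10 ± 1.01 in PEO4 (adjusted p = 1.3e-07 and 0.000723). MFAP5, a microfibril protein, stood at 83.1, 44.2 and 26.8 in PEO14 and at 0.702, 0.878 and 1.68 in PEO23 (adjusted p = 1.29e-12).

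Glycolysis genes differed in direction between pairs, a difference that was not itself tested. At 24 h, of 23 genes, 11 were lower and 1 higher in PEA2, 4 lower and 0 higher in PEO23, and 6 higher and 1 lower in PEO4 (median -0.62, -0.74 and 0.80, adjusted p = 0.00122, 0.00835 and 0.0281 with an estimated correlation). At 8 h the medians were -0.79 in PEA2, -0.59 in PEO23 and 0.28 in PEO4 (adjusted p = 0.00165, 0.00944 and 0.141 with an estimated correlation). These directions were the same with TPM as deposited, with medians of -0.62, -0.52 and 0.62 at 24 h and -0.79, -1.36 and 0.11 at 8 h. NF-kB and cytokine genes were higher in PEA2 at 24 h, 13 of 29 against 2 lower (adjusted p = 0.00496 with an estimated correlation), and lower in PEO4, 10 against 2 higher (adjusted p = 0.0108 with an estimated correlation). Mesenchymal genes were lower in PEO23 at 8 h, 11 of 23 against none higher (adjusted p = 0.00792 with an estimated correlation). Between 8 h and 24 h RGS2, a regulator of G protein signalling, rose by 3.59 ± 0.72 in PEO14 and changed by -4.12 ± 0.76 in PEO4 (adjusted p = 0.00601 and 0.00184), and PMAIP1, encoding the BH3 protein NOXA, rose by 3.17 ± 0.59 in PEO14 and changed by -2.16 ± 0.62 in PEO4 (adjusted p = 0.00328 and 0.0223), with 1 kept library at 24 h in each line. With the replicate number as a block each of these contrasts compares 1 library with 1, replicate 2 in PEO4 and replicate 1 in PEO14. The block therefore gives no check of RGS2 or PMAIP1 on replicates.

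Libraries from treated cultures held less MALAT1 and NEAT1 and more ribosomal protein mRNA than untreated ones in the 5 lines with kept untreated libraries. Less nuclear RNA in the treated libraries was tested with lists of 12 nuclear and 12 cytoplasmic noncoding RNAs. Their median changes differed by -0.44, -1, -2.21, -2.47 and -1.59 in PEA1, PEA2, PEO1, PEO4 and PEO14. In PEA1 this fell short of the difference of -1 that the explanation needs in every line. The nuclear medians were 0, -0.08, 0, -0.29 and -0.76 in the same order, and the cytoplasmic medians lay from 0.44 to 2.21. These medians hold with rescaling. In the same libraries the median change of all genes was -0.155 in PEO1 and -0.235 in PEO4 with rescaling, and -1.144 and -1.124 without it. How far each difference came from lower nuclear or higher cytoplasmic RNAs therefore depends on the scaling and cannot be told here. Transcript length gave rank correlations with the change of -0.19, -0.094, -0.21, -0.18 and -0.15 over 16365 genes, short of -0.3 in all 5 lines, yet below -0.1 in 4 of them. Passages overlapped in 1 of 18 pairs of cultures, so passage, day or library batch cannot be told apart from treatment. All 3 explanations stay open, as does an untested response of the cells to carboplatin.

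The library labelled PEA1 untreated replicate 3 lay closest to PEA2. Few genes alone did not lead to this in most cases, since 2 of the other 11 libraries with few genes lay closest to another line. Yet all 3 libraries closest to another line listed few genes. A part of few genes is therefore not excluded in PEA1 untreated replicate 3. Of 565 genes that separate the lines and were above 0 there, 82.3% lay closer to untreated PEA2, against 17% of 640 in PEA1 untreated replicate 2 and 84.8% of 624 in PEA2 8 h replicate 2. A candidate explanation is RNA of PEA2 in that library, by a wrong label or a mixture, which these values do not tell apart. No biological explanation was tested.

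Interferon-stimulated genes were called higher in the resistant lines in 8 of 8 comparisons of kept libraries at the preset correlation. With an estimated correlation the call held in all 5 for PEO4 and PEO23 and in none of 3 for PEA2, where the list medians were 0.88, 0.71 and 0.59 (adjusted p = 0.186 untreated, 0.319 at 8 h and 0.266 at 24 h). These 8 values come from a fit without libraries listing few genes, which argues against such libraries as the cause. Rescaling of the TPM values is argued against by list medians of 0.6 to 2.03 with TPM as deposited. As a hypothesis from the same data, a difference between the lines may underlie the pattern in PEO4 and PEO23, where resistance itself, a difference between sublines unrelated to it and culture history stay open and untested.

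For the other results the 6 libraries of a comparison make 10 splits, too few for a share under 0.05. The real count and the highest other, for 1 split as large, were 701 and 337 in PEA2, 874 and 79 in PEO4, and 6946 and 4221 in PEO23 without drug. At 8 h they were 480 and 43 in PEA1, 578 and 11 in PEA2, 821 and 66 in PEO1, 1851 and 398 in PEO4, 951 and 6 in PEO14, and 6498 and 4779 in PEO23. At 24 h they were 416 and 55, 413 and 7, 614 and 3, 2039 and 936, 2886 and 51, and 6517 and 4898 in the same order. Between 8 h and 24 h they were 2 and 2 in PEA1 (2 splits as large), 0 and 2 in PEA2 (10), 5 and 2 in PEO1 (1), 150 and 4134 in PEO4 (3), 154 and 739 in PEO14 (2), and 11 and 20 in PEO23 (3), and the highest splits of PEO4 and PEO14 point to a structure of the samples. Of these 10 splits, 4 part all 3 pairs of cultures that share a passage, and among them the highest other was 1 in PEA1, 1 in PEA2, 2 in PEO1, 467 in PEO4, 20 in PEO14 and 7 in PEO23, while the splits that part 1 pair reached 2, 2, 2, 4134, 739 and 20. Results over several lines had 100 splits, of which 1, the real one, was as large for the 13 genes lower in all 6 lines at 8 h and the 12 at 24 h (highest other 0 for each). Each line was split separately, so a split seldom parts treated from untreated libraries in all 6 lines, and a 0 was nearly fixed in advance. Both counts also fell to 0 without replicate 2. The splits therefore do not exclude chance for these counts. For the 2 genes lower in all 3 pairs the real split was also the 1 as large (highest other 1), but independent lists of the same sizes would share 1.14, and limma gave 0 with a pseudocount of 0.1, with only the compared groups in the model, without replicate 1 and without replicate 2, so an overlap by chance was not excluded.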
